A study of Mus musculus with 6 samples.

How the data were processed

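The study measured polyadenylated RNA of heart ventricles from wild-type CD-1 mice at 1 day (P1) and 2 days (P2) after birth, with 3 libraries per age, sequenced on an Illumina HiSeq instrument. Groups and replicate numbers were taken from the sample titles. The authors deposited 1 table of FPKM values, with a column for each of the 6 libraries and a row for each of 39171 Ensembl mouse genes, and all columns were used. Per the submitters' processing notes, the tools were FastQC, TopHat2, Cuffdiff 2.2.1 and R 3.2. The genome build, the annotation release, any filter, whether fragments were assigned by strand, and any scaling between libraries are not given in the sources used here. Symbols were assigned from the GENCODE M21 annotation of GRCm38, in which 37605 gene identifiers had a symbol and 1566 did not. Positions and overlapping genes are given as in that annotation.

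FPKM values divide by transcript length and by the fragments of the library, so they do not hold the counts on which a count model would rest, and the precision of each value from counting is unknown. Relative depth was read from the smallest values: among genes below 0.05 FPKM in both libraries, the value of 1 fragment was compared with that in P1 replicate 1. This was the median ratio over genes, after ratios far from 1 were left out. Short RNA classes and mitochondrial ribosomal RNA held between 37.8% and 46.7% of the FPKM sum per library. Because short transcripts get large FPKM values, the sum is sensitive to them. Values were used as deposited. In the table, 14900 genes were at 0 in all libraries. Some abundant heart transcripts were among them, so an exact 0 may stand for an estimate that failed, and such genes are described as listed at 0.

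The main test was limma (version 3.58.1, R 4.3.3) on log2(FPKM + 1) with the age as the only factor, moderated variances with a trend, and Benjamini-Hochberg adjustment over the genes with a mean of at least 1 FPKM (13624 genes). A gene was called at an adjusted p under 0.05, two-sided. The median residual SD of the log2 values was 0.083. Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 32 of 35 lists that had at least 5 tested members, and beside it with camera with an estimated correlation and with fry. Fry asks whether the genes of a list move one way on balance and does not compare the list with other genes. Values are given as mean ± SD of FPKM over 3 libraries and log2 changes with their standard error. Changes are P2 minus P1. The share of genes whose ages do not overlap was set against the 10% that chance gives for 3 against 3.

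The test, the lists and the rule for named genes were fixed before the data were examined. The rule named up to 12 called genes per direction with the largest change and no overlap between ages. It named up to 4 called members of each list, or up to 2 with the smallest p where none was called, and a fixed set of heart genes whatever their p. Genes with provisional symbols, such as those starting with Gm, were counted and not named, apart from 2 named after their values were seen. Further members of called lists that passed 0.05 adjusted over the list alone were named after their values were seen, as were single genes shown per library.

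Each result was recomputed under other settings. These were a pseudocount of 0.1, no filter and a filter of 5 FPKM, rescaling to an equal FPKM sum, median ratio scaling, quantile normalization, no variance trend, array quality weights, the replicate number as a block, summed symbols, a threshold of 0.10, and each library left out in turn. Added after the data were seen were fits without genes listed at 0 in every library of 1 age, without genes listed at 0 in any library, without X- and Y-linked genes and with an atrial score as a covariate. The lists without their shared members or without Tnnt2 were also added then. The atrial score is the mean log2 value of the atrial list without Bmp10. Genes sharing fragments with an overlapping gene or pseudogene were kept and are uncertain.

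The steps were tested on simulated data with the observed means and residual spreads of 13624 genes and normal noise. Of genes given a log2 change of 0.5, 80.6% were recovered, and of those given 1 or 2, 98.5%, with 15 of 213 calls among genes given no change. A planted list was found, and 0 of 34 random lists were called. Changes were planted only in genes with a mean log2 value above 2. The noise was drawn independently for each gene, so the simulation does not test camera on lists whose members vary together. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.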

Results

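Poly(A) RNA was sequenced from the ventricles of wild-type CD-1 mice, an outbred laboratory stock, at 1 day after birth (P1, 3 libraries) and at 2 days after birth (P2, 3 libraries). The values are FPKM, fragments scaled by transcript length and by the mapped fragments of the library, for 39171 mouse genes. The table holds no read counts, so the absolute depth is unknown. Among genes below 0.05 FPKM, the value of 1 fragment relative to P1 replicate 1 lay between 0.934 and 1.10 in the other libraries. Ratios far from 1 were left out before the median was taken, so these values were bound to lie near 1. They do not show how close the depths of the 6 libraries are. Between 13355 and 13429 genes reached 1 FPKM per library. The FPKM sum was 716968, 754510 and 746690 in P1 replicates 1 to 3 and 832345, 807632 and 858436 in P2 replicates 1 to 3. Transcripts of the mitochondrial chromosome held between 30.8% and 39.5% of these sums. Because 11 of its 13 protein-coding genes were listed at 0 in all libraries, this share is not the whole mitochondrial fraction. Nothing in the labels ties a library to a separate animal beyond the statement of 3 hearts per age, so the p-values measure the spread between these samples, whether biological or technical.

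The comparison of P2 with P1 asks which ventricular transcripts differ between the first days after birth, a period in which the regenerative response of the neonatal mouse heart is studied. Few genes passed the test, and their changes were moderate. Of 13624 tested genes, 22 passed a Benjamini-Hochberg adjusted p of 0.05 in limma, 10 of them higher and 12 lower in P2. Among these, 3 of the higher genes were listed at 0 in every P1 library, which leaves 7 that rose and 12 that fell between measured levels. Among the genes that rose were Ush1c, the tubulin gene Tuba4a, the muscle gene Ankrd23 and the membrane repair gene Trim72, with log2 changes from 0.92 to 1.48. Among those that fell were the clock genes Tef and Per3, the growth factor gene Bmp10, the triglyceride synthesis gene Dgat2 and the mitochondrial carrier gene Ucp2, with log2 changes from -0.92 to -0.63.

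Beyond these calls, 2536 genes had an unadjusted limma p under 0.05, against 681.2 expected by chance, with 1461 higher and 1075 lower in P2. This split was 1359 and 1338 with median ratio scaling, 1325 and 1419 with quantile normalization and 166 and 5154 with equal FPKM sums. All P2 values lay above all P1 values for 14.4% of the tested genes and below them for 10.6%, where chance gives 10% for both directions together. An exact permutation test of 3 against 3 cannot go below p = 0.10, so no single gene can be called that way. Correlations of log2 values between libraries of 1 age (0.916 to 0.936) covered the same range as those between ages (0.917 to 0.932). Rescaling each library to an equal FPKM sum moved the median log2 change of all genes from 0.01 to -0.14 and the calls to 40 higher and 2420 lower. The number of calls fell to 5 without P1 replicate 1 or P1 replicate 2, to 11 without P2 replicate 1 and to 12 without P2 replicate 2. It was 17 without P2 replicate 3 and 25 without P1 replicate 3.

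Among called genes with measured levels at both ages, the largest rise was that of Ush1c (ENSMUSG00000030838), which encodes the scaffold protein harmonin. Its level was 4.96 ± 0.914 FPKM in P1 and 15.5 ± 1.502 in P2 (SD, n = 3 each), a log2 change of 1.48 ± 0.13 (SE; limma, Benjamini-Hochberg adjusted p = 0.0294). In the GENCODE M21 annotation of GRCm38 it lies on chromosome 7 from 46195350 to 46238503. Tuba4a, an alpha-tubulin gene, rose by 1.03 ± 0.09, from 53.1 ± 4.42 to 110 ± 10.2 FPKM. Ankrd23, which encodes a titin-binding ankyrin repeat protein of muscle, rose by 1.01 ± 0.08, from 21.7 ± 1.74 to 44.5 ± 3.65 FPKM. Trim72, the membrane repair protein also called MG53, rose by 0.92 ± 0.09, from 6.97 ± 0.181 to 14.1 ± 1.72 FPKM. Smaller rises were found for the Notch-responsive transcription factor Hey1 (0.47 ± 0.05) and for Itga7, the alpha subunit of a laminin-binding integrin of muscle (0.41 ± 0.04). All log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes at low levels. Of these 6 genes, 0 were called by limma without P1 replicate 1 (Benjamini-Hochberg adjusted p from 0.106 to 0.172), without P1 replicate 2 (0.0672 to 0.144) or without P2 replicate 2 (0.0526 to 0.158). Ush1c, Tuba4a and Ankrd23 were called without P1 replicate 3, Trim72 alone without P2 replicate 1 and Tuba4a alone without P2 replicate 3, with the others between 0.0583 and 0.210. Hey1 and Itga7 were not called with median ratio scaling, quantile normalization or no filter, nor was Trim72 with no filter.

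The gene with the smallest adjusted p between measured levels was Tef (ENSMUSG00000022389), a transcription factor of the clock output. Tef fell from 32.9 ± 0.196 to 20.1 ± 0.296 FPKM, a log2 change of -0.69 ± 0.03 (limma, Benjamini-Hochberg adjusted p = 0.00222), and kept its call without any 1 of the 6 libraries. It lies on chromosome 15 from 81802421 to 81826863 in the GENCODE M21 annotation of GRCm38. Among the called genes, the largest fall was that of Bmp10, a growth factor gene of the heart, from 3.32 ± 0.284 to 1.28 ± 0.120 FPKM (log2 change -0.92 ± 0.08). The clock gene Per3 followed with -0.88 ± 0.09. Pop4, a subunit of ribonuclease P, fell by 0.71 on the log2 scale. Dgat2, which makes triglycerides, fell from 37.9 ± 2.18 to 23.3 ± 1.13 FPKM, and Retsat, retinol saturase, from 28.9 ± 0.269 to 17.7 ± 1.40. Ucp2, a carrier of the inner mitochondrial membrane, fell from 184 ± 3.15 to 119 ± 6.26 FPKM (log2 change -0.63 ± 0.05). The galectin gene Lgals4 (-0.65), the kainate receptor subunit Grik5 (-0.46), the choline kinase Chkb (-0.42), the microfibril-associated Adamtsl4 (-0.42) and the actin-oxidizing enzyme Mical1 (-0.40) also fell. Apart from Tef, none of these 12 genes was called by limma without P1 replicate 1 (Benjamini-Hochberg adjusted p from 0.0652 to 0.172) or without P1 replicate 2 (0.0577 to 0.157). Pop4 and Retsat were also called without P2 replicate 1 or P2 replicate 2, Pop4 and Ucp2 without P2 replicate 3, and Chkb, Dgat2, Per3, Pop4 and Ucp2 without P1 replicate 3, with the others between 0.0573 and 0.210. Per3, Lgals4 and Mical1 were not called with median ratio scaling, quantile normalization or no filter, nor were Grik5 and Adamtsl4 with no filter.

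**Figure D1:**
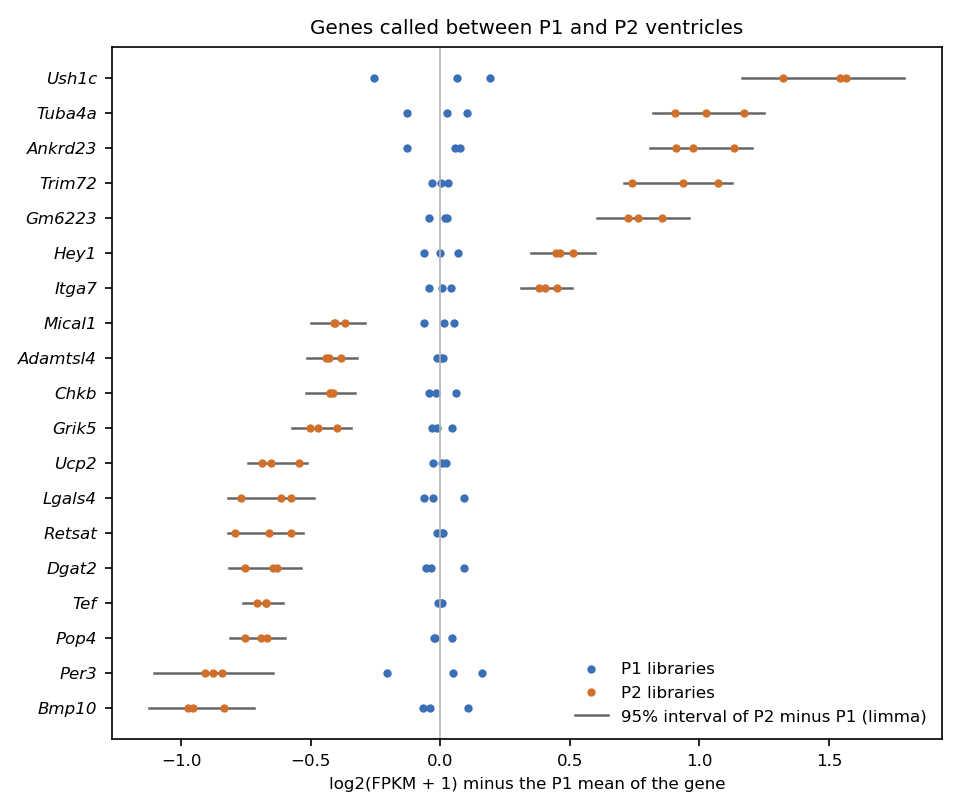
Values of the 19 called genes with measured levels at both ages, as log2(FPKM + 1) minus the P1 mean of each gene, with 1 point per library (blue, P1; orange, P2) and a grey bar for the 95% interval of the P2 minus P1 change from limma. The intervals do not reach 0, and the changes run from -0.92 for Bmp10 to 1.48 for Ush1c.

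Several called genes overlap others in the GENCODE M21 annotation, and whether the counting used strand is not given in the sources used here. Tef overlaps the antisense gene Gm17597, Ucp2 overlaps Dnajb13 and Tuba4a overlaps Stk16, each on the opposite strand. On its own strand, Per3 overlaps Camta1, Chkb overlaps Gm44502, Ankrd23 overlaps Gm42417 and Itga7 overlaps the small nuclear RNA gene Gm25494, so fragments from the shared stretches belong to either gene. Pop4, Trim72, Ush1c, Retsat and Mical1 overlap a gene on the opposite strand.

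Tnnt2, cardiac troponin T, was listed at 0 in all P1 libraries and at 3250, 2681 and 3172 FPKM in P2 replicates 1 to 3. A small nuclear RNA gene, Gm23865, and a small nucleolar RNA gene, Gm25777, which were chosen for naming after their values were seen, had the same form. No fold is given for these 3 genes, because abundant transcripts of this tissue were also listed at 0. Myh6, Actc1 and Myl2, major contractile genes of the heart, were at 0 in all 6 libraries, as were 11 of the 13 protein-coding genes of the mitochondrial genome. The remaining mitochondrial genes, mt-Nd2 and mt-Nd3, were measured at 9284 ± 308 and 10884 ± 717 FPKM in P1. Their P2 levels were 11121 ± 1892 and 12756 ± 113 FPKM, and neither passed limma's test. The log2 change of mt-Nd3, 0.23 as deposited, was -0.15 after quantile normalization. Leaving out every gene listed at 0 in any library, an alternative chosen after the data were seen, raised the calls to 49 higher and 62 lower, with all 19 calls between measured levels among them.

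Gene lists fixed beforehand were tested as groups with limma's camera at a preset correlation of 0.01. Of 32 lists with at least 5 tested members, 12 passed a Benjamini-Hochberg adjusted p of 0.05. A grouping that mixes the ages, P1 replicate 1 with P2 replicates 1 and 3 against the rest, also gave 12 called lists. The other groupings that mix the ages gave 2, 5, 4, 11, 7, 11, 10 and 2. Camera with the preset correlation thus also called lists where the groups were not the ages, and the list p-values below carry this limit. The number of called lists alone therefore does not set the ages apart. The mitotic, interferon and matricellular lists, and the mature heart muscle list, were higher in P2. The lists for fatty acid oxidation, PPAR and fasting response, the clock, basement membrane, fetal heart muscle, and atrial, epicardial and lymphocyte or granulocyte markers were lower. No list was called with an estimated correlation. With fry, which tests each list by itself, the clock list was called, and the mature heart muscle list with Tnnt2 but not without it. With equal sums, where the median of all genes was -0.14, the median of each called list stayed on its side of that of all genes, but 6 of the 12 lists were not called. These were the clock, mature and fetal muscle, atrial, epicardial and lymphocyte lists, with adjusted p from 0.136 to 0.290. Every list that was not called and had a positive median had a negative one with equal sums, and those of the integrin and hypoxia lists were also negative with median ratio scaling. With quantile normalization the medians of the integrin, hypoxia, glycolysis and oxidative phosphorylation lists were negative.

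**Figure D2:**
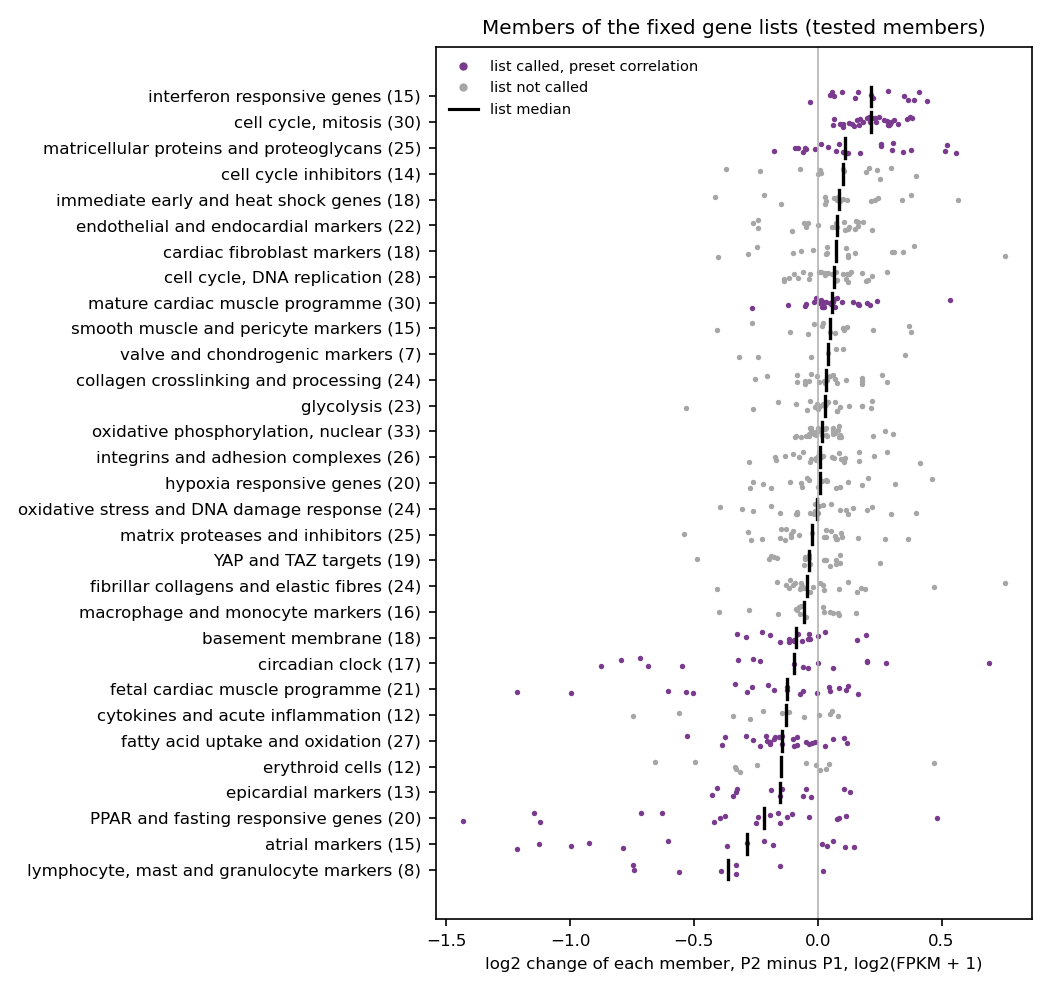
Change from P1 to P2 of each tested member of 31 tested gene lists (1 point per gene, log2(FPKM + 1), number of tested members in brackets), with the list median as a black line, called lists in purple and others in grey. Tnnt2 and the list of sex-linked transcripts are not drawn, and all 30 mitotic genes lie above 0 (20 with equal sums) while 23 of the 27 fatty acid oxidation genes lie below it.

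Among matrix genes, matricellular proteins and proteoglycans were higher in P2 as a group (18 of 25 tested members, median log2 change 0.11, camera adjusted p = 0.00226). The adjusted p ranged from 1.54e-09 to 0.570 over the alternatives, the highest with an estimated correlation. The median was -0.06 with equal sums, against -0.14 for all genes. None of these members passed over all genes, and 8 were higher adjusted over the list alone. The small proteoglycans Aspn (39.4 ± 4.77 against 58.3 ± 3.07 FPKM), Ogn (38.8 ± 4.16 against 55.6 ± 0.0733) and Dcn (189 ± 13.3 against 240 ± 13.1) had log2 values 0.56, 0.51 and 0.35 higher in P2, and Ccn3 was 0.52 higher. Basement membrane genes were lower (14 of 18, median -0.09, camera adjusted p = 0.00601), with an adjusted p of 0.487 with an estimated correlation and 0.00428 at the lowest over the alternatives. None passed over all genes. Adjusted over the list alone, Col4a6 (-0.32 ± 0.06) and Lama5 (-0.29 ± 0.08) were lower, while Nid1 (0.16 ± 0.04) and Smoc2 (0.19 ± 0.05) were higher. The value of Nid1 was -0.01 with equal sums.

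The other matrix lists did not pass camera. Fibrillar collagens and elastic fibre genes had an adjusted p of 0.621 (0.00880 with the atrial covariate, where the median was 0.09, and up to 0.977 over the alternatives), and their median (-0.04) and mean (0.02) differed in sign. Adjusted over the list alone, Mfap5 was higher (22.5 ± 2.32 against 38.7 ± 3.40 FPKM) and Ltbp1 lower (20.02 ± 0.0809 against 14.9 ± 0.860). The fibrillar collagen genes Col1a1 (220 ± 24.7 against 204 ± 11.6 FPKM) and Col3a1 (466 ± 33.8 against 510 ± 67.4) differed by less than the spread between replicates, and so did Fn1, with log2 changes of -0.10, 0.12 and -0.05. For Postn the values were 303 ± 12.4 and 332 ± 46.8 FPKM, a log2 change of 0.12 ± 0.11. The value of Col3a1 and that of Postn were each -0.05 with equal sums. Lox, the collagen crosslinking enzyme lysyl oxidase, was at 10.6 ± 1.06 in P1 and 11.2 ± 0.778 FPKM in P2, a log2 change of 0.07 ± 0.08 that was -0.09 with equal sums. Its list, collagen crosslinking and processing, had an adjusted p of 0.513, and adjusted over the list alone the collagen chaperone Serpinh1 was higher (225 ± 4.78 against 274 ± 3.06 FPKM) and Fkbp10 lower. Matrix proteases and inhibitors (adjusted p = 0.460), integrins and adhesion complexes (0.621) and YAP and TAZ targets (0.168) were not called either. Itga7 was the only one of 26 tested integrin list members that passed over all genes. In the protease list Adamts5 was 0.36 higher, and in the YAP list Gadd45b was 0.49 lower and Asap1 0.19 lower, none of them past the test over all genes.

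Mitotic genes were higher at P2 in all 30 members (median log2 change 0.21, camera adjusted p = 1.03e-06). The members varied together (estimated correlation 0.874), and the adjusted p ranged from 5.11e-13 to 0.679 over the alternatives, the highest with that estimated correlation. The ages were fully separated, with P2 higher, for 16 members. The share over all tested genes was 14.4% in that direction, where chance gives 10% for both directions together. Because the members varied together, they are not 30 separate observations. With equal sums, 20 of the 30 were higher and the median was 0.06. No single member passed, over all genes or adjusted over the list alone. Ccnb1, a mitotic cyclin, was at 17.2 ± 2.22 in P1 and 22.3 ± 2.43 FPKM in P2 (log2 change 0.36 ± 0.12). Ube2c was at 50.9 ± 4.46 and 66.5 ± 8.995, Cenpf at 7.16 ± 0.195 and 8.27 ± 0.0778, and the proliferation marker Mki67 at 19.8 ± 2.67 and 21.2 ± 1.71. The DNA replication list was not called (20 of 28 higher, adjusted p = 0.222; 0.0325 without P1 replicate 2, and up to 0.897 over the alternatives), with Mcm2 at 26.3 ± 0.624 and 29.9 ± 0.718 FPKM. Cell cycle inhibitors were not called (adjusted p = 0.201). Adjusted over that list alone, Ccng1, a p53 target, was higher (87.8 ± 5.69 against 116 ± 2.41) and Wee1 lower (15.8 ± 1.47 against 11.99 ± 1.01). Meis1, which restrains cardiomyocyte division, was at 22.9 ± 0.675 and 22.9 ± 0.0850 FPKM.

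Genes for the uptake and oxidation of fatty acids were lower at P2 in 23 of 27 members (median log2 change -0.14, camera adjusted p = 3.00e-07). The adjusted p of this list ranged from 6.97e-12 to 0.570 over the alternatives, the highest with an estimated correlation. None passed over all genes, and 9 were lower adjusted over the list alone. Their values included 50.6 ± 2.92 against 38.8 ± 1.71 FPKM for Cpt1a, which controls entry of fatty acids into mitochondria, and 320 ± 12.6 against 283 ± 14.3 for Cpt1b, its muscle isoform. The mitochondrial thioesterase Acot2 was at means of 56.6 and 39.0 (log2 change -0.53 ± 0.08), and Mlycd, malonyl-CoA decarboxylase, at 47.0 ± 3.34 and 35.7 ± 1.31.

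The list of PPAR and fasting responsive genes was lower in 16 of 20 members (median -0.22, camera adjusted p = 2.57e-06). With an estimated correlation its adjusted p was 0.487, and the lowest over the alternatives was 3.68e-09. Ucp2 fell over all genes, and adjusted over the list alone 8 genes were lower and 1 higher. The widest gaps were those of Angptl4, an inhibitor of lipoprotein lipase (43.0 ± 11.9 against 15.01 ± 3.01 FPKM, log2 change -1.43 ± 0.24), Pdk4, which restrains pyruvate oxidation (104 ± 25.1 against 45.7 ± 6.33, -1.15 ± 0.20), and Ucp3 (18.9 ± 3.72 against 8.15 ± 1.76, -1.12 ± 0.19). None of these passed over all genes, with limma's Benjamini-Hochberg adjusted p at 0.102 for Angptl4 and 0.105 for Pdk4. The thioesterase gene Acot1 was at 37.0 ± 2.57 and 22.2 ± 2.73. Without the genes listed at 0 in any library, 7 members of this list fell over all genes, among them Pdk4, Angptl4, Ucp3, Acot1, Cpt1a and Ucp2. The list was also called without the members it shares with the oxidation list (18 genes, adjusted p = 4.43e-05, or 0.570 with an estimated correlation).

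Glycolysis (15 of 23 higher, adjusted p = 0.621), nuclear genes of oxidative phosphorylation (20 of 33 higher, 0.621) and hypoxia responsive genes (11 of 20 higher, 0.939) were not called, and with quantile normalization 9 of 23, 12 of 33 and 9 of 20 members were higher. Adjusted over the glycolysis list alone, Aldoc was lower (8.97 ± 0.576 against 5.91 ± 0.749 FPKM), and Ldha was at 479 ± 30.1 and 557 ± 20.3. Cox5a was at 476 ± 31.3 and 576 ± 59.8, and Ndufv1 at 367 ± 5.11 and 345 ± 5.48. In the hypoxia list Higd1a was at 37.4 ± 3.45 and 46.6 ± 2.28, and P4ha1 at 11.6 ± 0.206 and 13.2 ± 0.651.

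Clock genes were lower in 12 of 17 members (median -0.10, camera adjusted p = 0.00310). The adjusted p of this list was 0.487 with an estimated correlation, the highest over the alternatives, and 1.54e-04 at the lowest. With fry it was 0.00236. Tef and Per3 fell over all genes. Adjusted over the list alone, 8 were lower and 2 higher. The lower ones included Dbp, another clock output factor (10.5 ± 1.36 against 5.97 ± 0.349 FPKM), Per2 (5.05 ± 1.14 against 2.46 ± 0.284) and Nr1d2 (20.9 ± 1.54 against 13.97 ± 0.599), with log2 changes of -0.72, -0.79 and -0.55. Arntl, the positive clock factor BMAL1, stood on the opposite side with 2.04 ± 0.0897 in P1 and 3.94 ± 0.490 FPKM in P2 (log2 change 0.69 ± 0.09). With the genes listed at 0 in any library left out, 5 members fell and Arntl rose over all genes.

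The mature heart muscle list was higher in 24 of 30 members (median 0.06, camera adjusted p = 0.0102), but without Tnnt2, the only member past the test over all genes, it was not called (adjusted p = 0.0744, and 0.105 with fry). With all members its adjusted p was 0.487 with an estimated correlation, and ranged from 8.15e-04 with fry to 0.710 with quantile normalization. It was also not called without P1 replicate 3 (0.0565) or without P2 replicate 1 (0.123), and its median turned to -0.01 under quantile normalization and to -0.11 with equal sums. Adjusted over the list alone, Pln, the calcium pump regulator phospholamban, was higher (1690 ± 71.6 against 1992 ± 39.4 FPKM) and the calcium channel gene Cacna1c lower (50.3 ± 0.776 against 41.7 ± 2.30). Tnni3, cardiac troponin I, was at 2073 ± 24.3 and 2169 ± 76.3 FPKM, a log2 change of 0.07 that was -0.13 after quantile normalization and -0.11 with equal sums.

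Fetal heart muscle genes were lower in 15 of 21 members (median -0.13, camera adjusted p = 0.0204, or 0.487 with an estimated correlation, which was the highest over the alternatives, with 0.0105 the lowest). None passed over all genes, and adjusted over the list alone the imprinted gene Peg3 (35.9 ± 2.89 against 25.1 ± 2.80 FPKM) and the calcium channel gene Cacna1h (17.0 ± 1.44 against 13.2 ± 0.484) were lower. The list was not called without P1 replicate 1 (adjusted p = 0.0740), nor with the atrial covariate (0.265), nor without the 3 members it shares with the atrial list (18 genes, adjusted p = 0.125). Tnni1, the fetal troponin I, was at 1744 ± 62.7 and 1600 ± 38.8 FPKM, and Myh7, the fetal myosin heavy chain of the mouse, at 384 ± 79.8 and 367 ± 82.1. Neither passed the test.

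Interferon responsive genes were higher in 14 of 15 members (median 0.21, camera adjusted p = 8.23e-04), and in 9 of 15 with equal sums (median 0.07, against -0.14 for all genes). The adjusted p ranged from 4.06e-07 to 0.570 over the alternatives, the highest with an estimated correlation. None passed over all genes, and 5 were higher adjusted over the list alone. Isg15 was at 2.68 ± 0.294 and 4.03 ± 0.839 FPKM, Irf7 at 2.07 ± 0.265 and 3.02 ± 0.183, and Ifi27 at 13.7 ± 0.950 and 16.9 ± 0.838. Markers of lymphocytes, mast cells and granulocytes were lower in 7 of 8 members (median -0.36, camera adjusted p = 0.00219, or 0.511 with an estimated correlation, with a lowest value of 6.05e-05 over the alternatives). The members with the smallest p were the neutrophil genes S100a9 (12.4 ± 3.37 against 6.90 ± 1.37 FPKM) and Retnlg (1.68 ± 0.599 against 0.583 ± 0.217), neither past the test. Macrophage and monocyte markers (adjusted p = 0.222) and cytokines and acute inflammation (0.0691) were not called. The macrophage list was called without P2 replicate 3 (0.0499, and up to 0.847 over the alternatives), and the cytokine list without P1 replicate 1 (0.00916) or P2 replicate 3 (0.0300), with a range from 0.00621 to 0.723. Example values were 3.07 ± 0.111 and 2.36 ± 0.134 FPKM for Fcgr3 and 2.72 ± 0.0477 and 2.10 ± 0.451 for Ccl2.

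Immediate early and heat shock genes were not called (15 of 18 higher, adjusted p = 0.150), except with no filter (23 members, 0.0161, and up to 0.646 over the alternatives). Adjusted over the list alone, the flow-responsive factor Klf2 was higher (14.7 ± 0.825 against 19.4 ± 1.28 FPKM) and Myc lower (6.95 ± 0.402 against 4.98 ± 0.535). Oxidative stress and DNA damage genes were split evenly (12 higher and 12 lower, adjusted p = 0.939), with a median of -0.0044 and a mean of 0.0017. Catalase (Cat) was at 67.6 ± 1.30 and 59.2 ± 1.28 FPKM.

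Marker lists of the other cell types of the ventricle were compared in the same way. Cardiac fibroblast (12 of 18 higher, adjusted p = 0.166), endothelial (15 of 22 higher, 0.201), smooth muscle and pericyte (10 of 15 higher, 0.495) and valve markers (4 of 7 higher, 0.966) were not called. The fibroblast list was called without P2 replicate 2 (0.00468) and with the atrial covariate (4.75e-05), with a highest value of 0.808 over the alternatives. Example values were 8.49 ± 0.380 and 11.4 ± 0.407 FPKM for the fibroblast surface marker Thy1, 75.7 ± 3.82 and 85.9 ± 3.66 for the endothelial gene Cdh5, 15.1 ± 0.444 and 12.6 ± 1.29 for Apln, and 72.4 ± 4.89 and 93.7 ± 6.25 for the pericyte gene Rgs5. In the valve list Matn2 was at 10.9 ± 0.981 and 14.2 ± 0.728 and Matn4 at 2.59 ± 0.239 and 2.04 ± 0.287, and that list's median (0.04) and mean (-0.0028) differed in sign. Epicardial markers were lower in 11 of 13 members (median -0.15, camera adjusted p = 0.0204, or 0.679 with an estimated correlation, with a lowest value of 0.00293 over the alternatives). No epicardial gene passed, and the list was not called without P1 replicate 2 (adjusted p = 0.0585, median -0.06), P1 replicate 3 (0.0565, -0.13) or P2 replicate 2 (0.0967, -0.18). It was also not called with a filter of 5 FPKM (0.148) or with the atrial covariate (0.265), where its median was -0.18. Msln was at 12.1 ± 0.478 and 8.97 ± 1.56 FPKM and Upk1b at 2.89 ± 0.208 and 1.91 ± 0.324. Erythroid genes were not called (8 of 12 lower, adjusted p = 0.0691), but were called without P1 replicate 2 (0.0234), P2 replicate 1 (0.0325) or P2 replicate 2 (0.0171), and with the atrial covariate (0.00171), with a range from 0.00171 to 0.745 over the alternatives. Adjusted over the list alone, the globin genes Hba-a2 (5.43 ± 0.397 against 3.57 ± 0.438 FPKM) and Hbb-bt (151 ± 29.5 against 94.5 ± 6.35) were lower and the transferrin receptor Tfrc higher (64.7 ± 7.30 against 89.6 ± 1.28), and Hba-a1 was at 316 ± 61.4 and 254 ± 44.3. Lists with fewer than 5 tested members were not tested as groups. Mbp, a myelin gene of Schwann cells, was at 1.27 ± 0.111 and 1.06 ± 0.0740 FPKM, and the skeletal muscle gene Mylpf, a neighbouring tissue marker, at 2.03 ± 0.938 and 1.03 ± 0.279.

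Atrial markers were lower in 10 of 15 members (median -0.29, camera adjusted p = 0.00310, or 0.570 with an estimated correlation, and between 5.18e-05 and 0.872 over the alternatives). Bmp10 was the only member that fell over all genes. Some other atrial genes differed strongly between libraries of the same age. Sln, sarcolipin, was at 48.5, 27.6 and 37.4 FPKM in P1 replicates 1 to 3 and at 17.6, 5.76 and 40.5 in P2 replicates 1 to 3, and Myl7, the atrial myosin light chain, at 471, 314 and 411 and at 199, 103 and 369. Nppa, which is also made in the ventricle of newborn mice, was at 421, 286 and 281 and at 177, 336 and 160 FPKM (log2 change -0.61 ± 0.31, not past the test). With the mean level of the other atrial genes as a covariate, an alternative added after the data were seen, 2 genes were called and neither was Bmp10, whose log2 change was -0.854 (95% interval -1.17 to -0.538) there, against -0.92 without the covariate.

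The sex-linked transcripts were not called (adjusted p = 0.436) but divided the P2 libraries: the P1 libraries and P2 replicate 1 had Y-linked transcripts and almost no Xist, P2 replicate 2 the reverse, and P2 replicate 3 both. Sex therefore goes partly with age, and P2 replicate 3 need not come from 1 animal. Eif2s3y, a Y-linked gene, was at 66.1, 67.4 and 68.3 FPKM in P1 replicates 1 to 3 and at 68.7, 0.214 and 63.5 in P2 replicates 1 to 3. Xist, the transcript of the inactive X chromosome, was below 0.2 FPKM in all P1 libraries and in P2 replicate 1, at 121 in P2 replicate 2 and at 10.3 in P2 replicate 3. Ddx3y and Kdm5d followed Eif2s3y. None of the 22 called genes lies on X or Y.

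**Figure D3:**
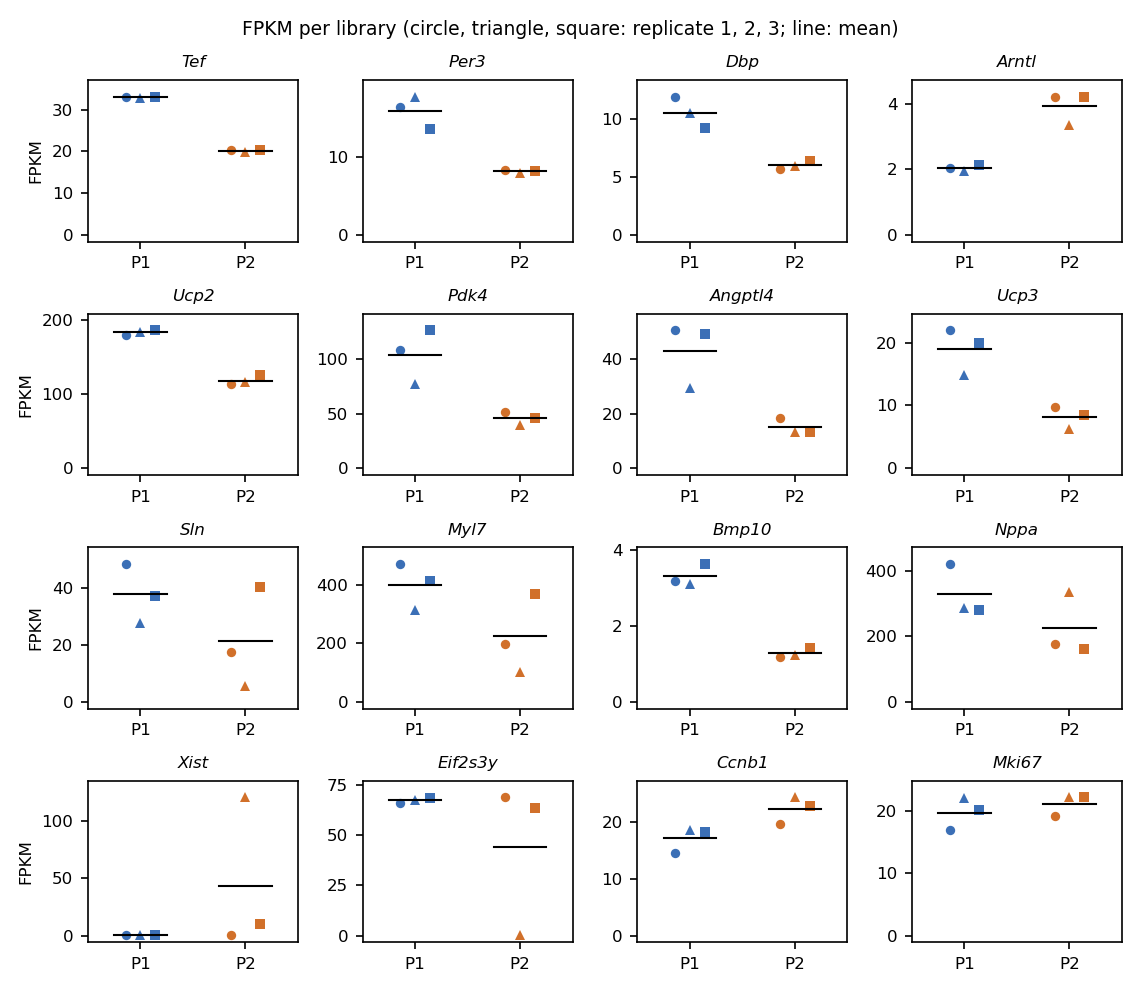
FPKM of 16 genes in each library (vertical axis, from 0), with circle, triangle and square for replicates 1, 2 and 3 and a line for the mean of each age. Tef and Ucp2 are separated between ages, Sln and Myl7 overlap, and Xist reaches 121 FPKM in P2 replicate 2 where Eif2s3y is at 0.214.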

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

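Tef stayed called when any 1 library was left out, and its log2 change ranged from -0.86 to -0.66 over all alternatives. The replicate block and the atrial covariate ended its call. Both fits have fewer residual degrees of freedom, as do those with 1 library left out, and why the call of Tef ended was not tested. The counts depended more on the settings, and apart from the cases named the cause was not tested. Leaving out 1 library gave between 2 and 13 genes called higher, between 2 and 12 called lower and between 10 and 14 lists. With 1 library fewer, P1 or P2 has 2 samples and the test less power. Against 10 higher and 12 lower genes as reported, there were 18 and 22 with a pseudocount of 0.1, 17 and 24 with a filter of 5 FPKM, 7 and 7 without the variance trend, and 50 and 54 at a threshold of 0.10, which is looser by construction. Rescaling to an equal FPKM sum gave 40 and 2420 genes and 6 lists, with the median of all genes at -0.14. Nuclear protein-coding genes summed to between 398176 and 406739 FPKM in P1 libraries and between 402631 and 420010 in P2 libraries. Short RNA classes and mitochondrial ribosomal RNA held between 37.8% and 41.4% of the whole sum in P1 and between 41.7% and 46.7% in P2. Dividing by the whole sum therefore lowered nuclear protein-coding genes in P2 relative to P1. Chosen after the data were seen, leaving out genes listed at 0 in any library gave 49 and 62, and the atrial covariate 2 and 0. Camera with an estimated correlation called 0 lists, with camera's preset at 12, and fry 2. The number with no filter, median ratio scaling, quantile normalization, array weights or summed symbols stayed within 1.5 times. Of the 22 genes called as reported, 17 stayed called with median ratio scaling and 17 with quantile normalization. Under both, Mical1, Itga7, Per3, Hey1 and Lgals4 were not called. With no filter 14 stayed called, without these genes and without Trim72, Grik5 and Adamtsl4. The share of genes with separated ages was 25.02%, or 26.4% with median ratio scaling and 26.3% with a filter of 5. The labels do not say whether the replicate numbers pair the samples. Deviations of same-numbered libraries correlated at -0.011, 0.101 and 0.0093, and not every library correlated best with its own number. With 3 libraries per age this check showed no clear pairing but cannot exclude a shared litter or batch. With a replicate block, 3 genes were called higher and 2 lower, 3 of them among the calls as reported, and 13 lists.

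Of the named genes called over all genes, none turned its sign under the alternatives run. With equal sums the genes that turned were Nid1 (-0.010), Lox (-0.089), Col3a1 (-0.048), Postn (-0.051), Tnni3 (-0.11), Mki67 (-0.062) and Meis1 (-0.16). Meis1 was -0.014 with median ratio scaling, -0.0068 with quantile normalization and -0.0037 with array weights, and quantile normalization also turned mt-Nd3 (-0.15) and Tnni3 (-0.13). The atrial covariate turned mt-Nd2 (-0.021), Kdm5d (0.41), Col1a1 (0.032), Fn1 (0.011), Myh7 (0.13), Meis1 (-0.0095), Ddx3y (0.85) and the atrial list median (0.11), which is built from the same genes. Leaving out 1 library gave ranges of -0.0015 to 0.18 for Mki67, -0.0038 to 0.13 for Lox, -0.012 to 0.024 for Meis1, -0.24 to 0.089 for Myh7 and -2.02 to 0.15 for Ddx3y. What depth limits cannot be read from FPKM values, which hold no counts.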

Other observations

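Of the tests below, those on Tnnt2, on the atrial markers, on Bmp10, on the scaling and the grouping of the clock genes and on the hour of collection were chosen only after the result was seen, as were the families in the next paragraph.

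Families outside the fixed lists gave small changes in both directions. Of the families considered, 2 more were left out because their members' values had prompted them. Of 81 tested cytosolic ribosomal protein genes, 62 were lower in P2 (median log2 change -0.04, limma's camera with Benjamini-Hochberg adjustment over 7 families, adjusted p = 0.00109), while 62 of 77 mitochondrial ribosomal protein genes were higher (median 0.05, adjusted p = 0.00112). With an estimated correlation the adjusted p was 0.511 for each. Of 17 genes of the unfolded protein response, 14 were higher (median 0.14, adjusted p = 0.00112, or 0.257 with an estimated correlation). Among them were the endoplasmic reticulum chaperones Hspa5 (157 ± 2.29 against 177 ± 8.23 FPKM, SD) and Hsp90b1 (119 ± 2.64 against 137 ± 5.83). Herpud1, whose value had been seen when the family was chosen, was at 46.8 ± 1.58 and 37.5 ± 1.22. No member of these families passed limma's test over all genes. With equal FPKM sums, where the median of all genes was -0.14, the median of the mitochondrial ribosomal list was -0.11 and that of the unfolded protein response -0.03. Proteasome (adjusted p = 0.457), chaperonin (0.538), cholesterol synthesis (0.615) and replication-dependent histone genes (0.418) were not called.

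Tnnt2 was listed at 0 in every P1 library and at 3250, 2681 and 3172 FPKM in P2. A rise of all contractile genes is argued against by the other tested members of the mature heart muscle list, whose median log2 change was 0.0536 with quartiles of 0.0145 and 0.142. Estimates that failed for very abundant transcripts are a candidate explanation, since 14 of 67 members of the heart muscle and mitochondrial genome lists were listed at 0 in all 6 libraries. Because major contractile genes such as Myh6, Actc1 and Myl2 were among those listed at 0, the 0 of Tnnt2 in P1 cannot be read as absence. These values therefore cannot tell whether Tnnt2 changed with age, and they are not evidence that it was switched on between P1 and P2.

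Several atrial markers differed between libraries of the same age, and Bmp10 fell between the ages. Different amounts of atrial tissue in the ventricular samples may account for the first, because 4 of 13 other atrial genes (Myl7, Stard10, Dkk3 and Mybphl) ordered the libraries within both ages as Sln did, against 1.58% of other tested genes (one-sided binomial p = 3.97e-05, which treats genes as independent). The library values of Sln, Myl7 and Nppa had been seen when this test was chosen, and without Myl7 and Nppa it gave 3 of 11 genes (one-sided exact binomial p = 0.000591). For Bmp10, the log2 change was -0.92 ± 0.08 (SE) before and -0.854 (95% interval -1.17 to -0.538) with the atrial score as a covariate, which argues against atrial tissue as the whole cause. Its call ended with the covariate (limma, adjusted p = 0.498, between 0.00506 and 0.498 over the alternatives). The fit with the covariate has 1 residual degree of freedom fewer and the score partly follows age, but why the call of Bmp10 ended was not tested. A change of Bmp10 with age was not tested and stays open.

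Clock output genes such as Tef, Per3 and Dbp were lower in P2 and Arntl higher, and when the clock list was divided, after its values were seen, into its opposed arms by textbook knowledge, 13 of 14 genes moved with their arm (two-sided binomial p = 0.00183), a count made on the genes that showed the pattern. Scaling between the libraries is argued against by log2 changes in opposite directions in the deposited values, -0.69 (95% interval -0.76 to -0.61) for Tef and 0.69 (0.48 to 0.91) for Arntl, since 1 factor per library moves all its genes alike; the gap between the arms' medians, at least 0.744 over these values and 3 other scalings, decides nothing, because such scalings can hardly change it. A different phase of the clock at collection may account for this pattern. A test on clock output genes outside the fixed lists was added after that count and before their values were seen. Its prediction was that all 5 would be lower in P2. Of these, 4 were lower, namely Usp2, Klf9, Tsc22d3 and Por, but not Coq10b (two-sided exact binomial p = 0.375). This test decides nothing, because 5 genes are too few for it to pass even if all were lower. Coq10b does not count against a shift of phase. Its log2 change was 0.08, with a 95% interval from -0.16 to 0.33 that covers both directions. The labels give an hour of collection for 0 samples, so the hour and the age cannot be told apart. A change of the clock with age also stays open as untested.

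For the number of called genes, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05, with 22 genes in the real split and at most 6 in any other, so that 1 split reached the real count. For lists, the 10 splits are also too few for such a share. The real split gave 12 lists and the others 2, 5, 4, 11, 7, 11, 10, 12 and 2, so that 2 splits reached 12, the real one among them. Unlike for genes, a split that mixes the ages gave as many calls as the real one. The number of called lists therefore does not set the ages apart.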
